A study of Mus musculus with 8 samples.

How the data were processed

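The samples were 8 single MII oocytes of superovulated mice, 4 from Setd1b conditional knockout females and 4 from control females, grouped by the genotype label of each sample. Per the labels' protocols, each oocyte was lysed, its RNA was reverse transcribed and amplified with the SMARTer Ultra Low kit, which primes on poly(A) tails, and a NEBNext library was sequenced as 75-bp single reads on an Illumina HiSeq. The kit does not mark the strand and carries no molecular identifiers, so amplified copies are counted as separate reads and counting intervals would cover counting error only. An mRNA with a short tail can be primed less well, so a measured level reflects both abundance and polyadenylation.

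Per the submitters' processing notes, the authors used GSNAP 2014-10-14, featureCounts 1.4.4, DESeq2 1.3.79 and the mouse build mm10. Per the file headers, the authors' counts per gene were made with featureCounts on Ensembl release 69 with a minimum mapping quality of 1, no strand setting and no option for multiply mapped reads. Reads of near-identical copies are therefore lost or split, and overlapping genes on opposite strands cannot be told apart. The deposited count table also gives the gene length. The authors' deposited comparison table holds shrunken and unshrunken log2 fold changes, a standard error of the fold change (a score without a fixed range), p-values and adjusted p-values, a normalized signal per library and RPKM values. It listed 2709 genes, none with an adjusted p above 0.009996. The normalized signal in the deposited table matched the counts divided by 1 size factor per library, from 0.815 to 1.24, to within 0.165 normalized counts, and the deposited RPKM values were recomputed from the counts, total counts and gene lengths to within 0.05. All tests here used the deposited counts, and the deposited fold changes and p-values were only set beside them.

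The table held 37224 genes, of which 18743 had no count in any library. Symbols came from a gene name table for 35449 identifiers and from the deposited comparison for 10, and 1765 stayed unnamed. The named genes held 99.9% of counts. Every value in the 8 count columns was a whole number of 0 or more. No row without a gene was present. Within a group, libraries correlated at 0.969 to 0.980 on log2(CPM + 1), and every pair differed by far more than sampling noise, with a chi-square per degree of freedom from 34.9 upwards, so no library was counted more than once. Totals ran from 9488899 to 13519404 counts, where the floor of 3 counts is 0.222 to 0.316 CPM before composition scaling.

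Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM factors, filterByExpr, genotype as the only term), and p-values were adjusted by the Benjamini-Hochberg method over 11066 genes, with a threshold of 0.05. CPM values use totals multiplied by TMM factors, which ran from 1.07 to 1.22 in knockout and from 0.799 to 0.946 in control libraries. The SE of a log2 fold change is its size divided by the square root of F. The fit was tested on simulated counts of the same 11066 genes, 4 against 4 libraries: 12 of 100 genes changed 2-fold and 59 of 100 changed 4-fold were recovered, and 5 unchanged genes were called. The required recovery was lowered after this result was seen, so the test was not passed at the level first set. The simulation changed 100 genes at each size, evenly up and down, far fewer than were called in the data. The adjusted p depends on that share, so the recovery is not the power in these data.

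Before the data were examined, 23 gene lists, the design, the rule for named genes and most alternatives were fixed. The list of factors named by the study had been chosen by the study on these samples, so its test is not independent of them. Of 461 members written, 7 matched no gene. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01, adjusted over the lists. The rule named Setd1b, the 10 largest rises and falls among called genes with a mean of at least 10 CPM, no overlap between groups and a plain symbol, the 5 most abundant called genes per direction, up to 4 members of each list by smallest p, and all factors the study names. Library measures were compared by exact two-sided permutation over 70 assignments.

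Alternatives were median-of-ratios size factors, library totals only, mitochondrially encoded genes left out, no filter, at least 10 CPM in 4 libraries, DESeq2 1.42.0, voom with library quality weights, the replicate number as a block, libraries thinned to 9488899 counts, each library left out in turn, an adjusted p of 0.01, a 2-fold minimum, and for lists an estimated correlation and the rotation test fry. Removal of a length trend, or a length and GC trend, per library (loess, span 0.5) was added after the data were seen. GC content and 3' untranslated regions came from GENCODE release M21. Python 3.11.15 with scipy 1.17.1 did the other tests.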

Results

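Single mouse oocytes arrested at metaphase of the second meiotic division (MII oocytes) were profiled by RNA sequencing. The 8 libraries fell into 2 groups of 4, oocytes from knockout females and oocytes from control females. The knockout females carried a conditional knockout of Setd1b named after Gdf9, a gene expressed in growing oocytes. Setd1b encodes a methyltransferase for lysine 4 of histone H3, and the comparison addressed how its loss in the growing oocyte alters the transcripts held by the mature egg. The total assigned counts were 10967753, 11313502, 10413775 and 9488899 in knockout replicates 1 to 4 and 11029602, 13519404, 12827443 and 12504464 in control replicates 1 to 4. The labels do not say whether oocytes of 1 group came from different females, so the p-values measure the spread between these oocytes and their libraries.

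Setd1b itself was lower in each knockout library than in each control library. The gene (ENSMUSG00000038384, chromosome 5, 123142193 to 123167435, mm10) had 4.43, 5.06, 2.97 and 3.54 counts scaled by library total and composition (CPM) in knockout replicates 1 to 4 and 10.7, 12.8, 9.24 and 10.9 CPM in control replicates 1 to 4. Its log2 fold change of knockout over control was -1.44 ± 0.41 (SE, n = 4 per group), with an adjusted p of 0.0221 in edgeR's quasi-likelihood test. The authors' deposited table gave a shrunken log2 fold change of -1.42, an unshrunken one of -1.49 and an adjusted p of 0.00011. The labels do not name the deleted part of the gene, so the counts that were left cannot be assigned to intact or deleted exons. The call rested on few counts, 197 in the knockout and 478 in the control libraries: the adjusted p was 0.0519 without knockout replicate 3 and 0.054 without control replicate 2, and 0.0895 with library totals as the only scaling (log2 fold change -1.04).

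Across the transcriptome, 1503 of 11066 tested genes were higher and 1347 were lower in knockout oocytes at an adjusted p under 0.05. The higher genes had a median of 19.0 CPM, against 15.7 CPM for all tested genes, and a median log2 fold change of 1.86, and the lower genes were more abundant, with a median of 144 CPM and a median log2 fold change of -0.97. At least a 2-fold difference was reached by 1281 of the higher and 623 of the lower genes. In 3459 tested genes, 31.3% of them, the libraries of the 2 groups did not overlap, against 2.86% given by chance. The share of calls in each direction depended on scaling: with library totals alone, 2382 genes were higher and 504 lower, and the median log2 fold change of all tested genes was 0.49 in place of 0.10. With a length trend removed from each library, an alternative added after the data were seen, 1217 were higher and 1827 lower, so neither direction can be said to prevail. Without knockout replicate 2, 1849 genes differed.

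**Figure D1:**
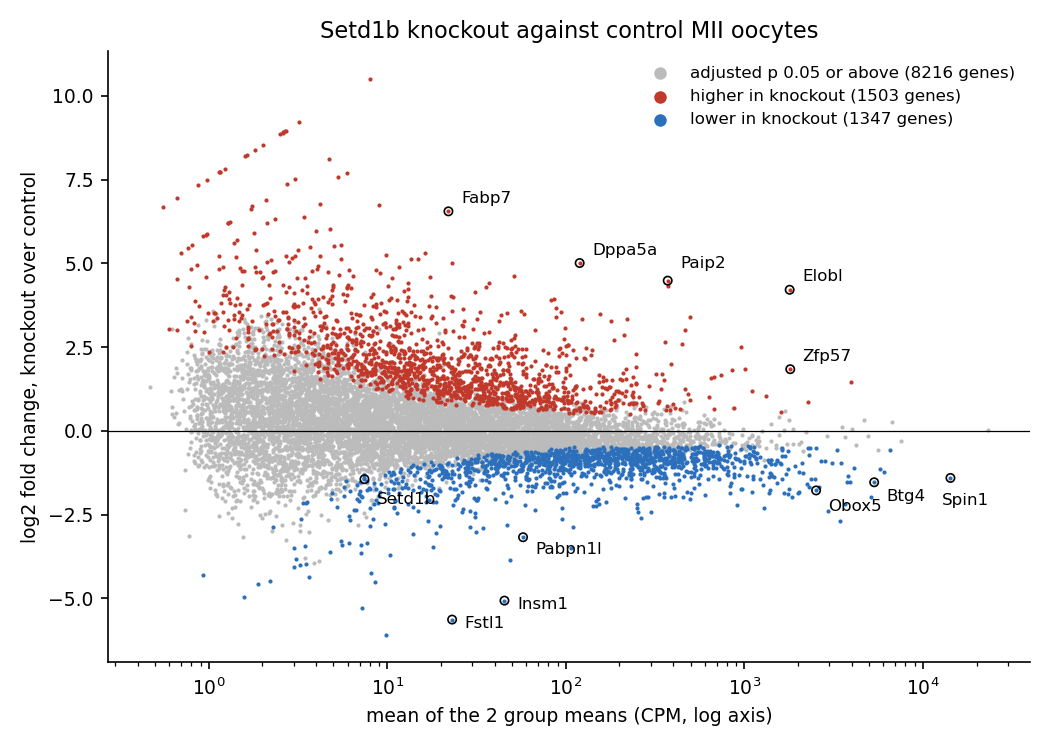
Each point is 1 of 11066 tested genes, with the mean of both group means in CPM on a log axis and the log2 fold change of knockout over control on the vertical axis. Red points are the 1503 higher and blue points the 1347 lower genes, and the lower genes lie towards the abundant end, with a median of 144 CPM against 19.0 CPM for the higher ones.

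Among called genes that met the rule for naming, the largest rise was that of Fabp7. This gene, which encodes a fatty acid binding protein of the brain, stood at 43.6 ± 8.97 CPM (SD, n = 4) in knockout and 0.447 ± 0.283 CPM in control oocytes, a log2 fold change of 6.55 ± 0.45 (SE; adjusted p = 1.086e-05). Dppa5a, a marker of pluripotent cells, rose from 7.22 ± 2.93 to 232 ± 44.6 CPM (log2 fold change 5.01). Paip2, which binds and restrains the poly(A)-binding protein, rose from 32.0 ± 25.3 to 713 ± 98.7 CPM (log2 fold change 4.48). The other genes named for the largest rises were Psmb7, Eif4h, Krt73, Slc16a6, Galk2, Gcat and Hist1h2bc, with log2 fold changes from 4.41 for Hist1h2bc to 5.14 for Psmb7. The control libraries together held only 20 counts of Fabp7, 34 each of Psmb7 and Krt73 and 36 of Gcat. The sizes and the order of these rises are uncertain for that reason. Several of these fold changes were larger with 1 control library left out. Without control replicate 1 the log2 fold changes were 5.19 for Paip2, 5.61 for Galk2 (4.60 with it) and 5.19 for Gcat (4.55 with it). Slc16a6 was at 5.32 without control replicate 2 (4.63 with it), and without control replicate 3 Eif4h was at 6.43 (5.01 with it) and Krt73 at 5.73 (4.88 with it). For Slc16a6, control replicates 2 and 4 were both high, at 8.32 and 6.61 CPM. Among the most abundant higher genes, the elongin B relative Elobl went from 184 ± 65.3 to 3407 ± 828 CPM, Ldhb from 2130 ± 532 to 5830 ± 1156 CPM, and Zfp57, a zinc finger protein that protects genomic imprints, from 790 ± 50.6 to 2829 ± 645 CPM. Skp1a and Prc1 rose by smaller amounts, with log2 fold changes of 0.85 and 0.57.

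By the same rule, the largest falls were in the secreted protein gene Fstl1 and the zinc finger gene Insm1. Fstl1 was at 45.3 ± 21.9 CPM (SD, n = 4) in control and 0.908 ± 0.862 CPM in knockout oocytes (log2 fold change -5.64 ± 0.74, adjusted p = 0.0003817), and Insm1 had a log2 fold change of -5.07 ± 0.41 (adjusted p = 2.229e-05). Pabpn1l, an oocyte poly(A)-binding protein needed to clear maternal mRNA, was at 104 ± 27.6 CPM in control and 11.5 ± 0.447 CPM in knockout oocytes (log2 fold change -3.18). Cth, S100a14, Arid5b, Epcam, Zfp423, Slc26a9 and Prr32 had log2 fold changes from -3.85 for Cth to -2.89 for Prr32. Without knockout replicate 4, Fstl1 was at -6.36 and S100a14 at -4.47 (-3.72 with it), and Zfp423 was at -3.81 without knockout replicate 3 (-3.07 with it). Among the most abundant lower genes, Spin1, a meiotic spindle-associated reader of histone methylation, went from 20745 ± 4000 to 7822 ± 2146 CPM and Btg4, which brings the CCR4-NOT deadenylase to maternal mRNA, from 7945 ± 1698 to 2739 ± 476 CPM. Bcl2l10, Mphosph6 and Zbed3 had log2 fold changes of -1.22, -1.13 and -0.57, and the fall of Zbed3 did not pass the threshold with library totals as the only scaling.

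Among genes of energy metabolism, translation and protein degradation, more rose than fell. Of 69 tested nuclear genes of oxidative phosphorylation, 36 rose and 1 fell (43 and 2 adjusted over the list alone), with a median log2 fold change of 1.239. Sdhd and Sdhc, subunits of succinate dehydrogenase, rose from 10.5 ± 1.25 to 155 ± 31.1 CPM (Sdhd) and with a log2 fold change of 2.10 (Sdhc), Cox6a1 had a log2 fold change of 3.59, and Ndufc2 rose from 9.35 ± 1.53 to 52.8 ± 12.1 CPM. Of 54 cytosolic ribosomal protein genes, 18 rose and 2 fell (21 and 2 adjusted over the list alone), with a median of 1.52. Rpl32 rose from 25.7 ± 7.73 to 171 ± 27.5 CPM. Rpsa, Rps3 and Rplp1 had log2 fold changes of 4.00, 4.03 and 2.46, and Rps3 was at 4.94 without control replicate 1. Of 33 proteasome genes, 16 rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 0.77. Psmd5, Psmb1 and Psma5 had log2 fold changes of 2.17, 2.61 and 2.24. limma's camera test of each list against the other genes gave adjusted p-values of 7.207e-10 for oxidative phosphorylation, 4.667e-05 for ribosomal proteins and 2.074e-06 for the proteasome. With an estimated correlation between genes the adjusted p-values were 0.251, 0.356 and 0.205, so none of the 3 calls held there. Ribosomal protein genes share near-identical sequence with many pseudogenes, and their counts are uncertain for that reason. Of the 10 tested genes encoded by the mitochondrial genome, 0 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.593), and mt-Co1, mt-Rnr1, mt-Rnr2 and mt-Nd6 had log2 fold changes of 0.32, 0.41, 0.26 and 0.25.

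The homeobox genes Obox1, Obox2, Obox5, Obox7 and Meis2 and the zinc finger gene Sall4, transcription factors named by the study, were lower in knockout oocytes, all 6 at an adjusted p under 0.05 and also adjusted over the list alone. The study chose these genes on these samples, so neither their count nor the test of their list is independent evidence of a direction. Their log2 fold changes were -1.84, -2.19, -1.78, -1.46, -1.89 and -1.36 in that order, and camera gave an adjusted p of 1.23e-07 (adjusted p = 0.205 with an estimated correlation). The Obox genes lie in a cluster of similar copies on chromosome 7, and reads can be split between them. Of 19 other oocyte transcription factors, 3 rose and 4 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.489). Nobox, a homeobox factor of the oocyte, rose from 84.3 ± 26.7 to 412 ± 119 CPM, Zfp143 rose from 18.9 ± 4.29 to 44.6 ± 14.2 CPM, Gtf2a1l had a log2 fold change of 0.96, and Tbpl2, the oocyte relative of the TATA-binding protein, had a log2 fold change of -2.69 ± 0.44 (SE).

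Maternal effect genes moved in both directions. Of 41 tested, 8 rose and 14 fell (10 and 15 adjusted over the list alone; camera adjusted p = 0.0595). Oog3 went from 5955 ± 1048 to 921 ± 155 CPM and Nlrp9b to 108 ± 18.2 CPM from a control mean of 434 CPM, both members of families with similar copies, while the ubiquitin-conjugating enzyme gene Ube2a had a log2 fold change of 2.15. Of 40 genes for storage and decay of maternal mRNA, 5 rose and 12 fell (6 and 13 adjusted over the list alone; camera adjusted p = 0.0595). Besides Btg4 and Pabpn1l, this list held the embryonic poly(A)-binding protein gene Pabpc1l and the poly(A) polymerase gene Papola, with log2 fold changes of 3.04 and 1.16. Of 19 genes of the zona pellucida, secreted products and the surface, 4 rose and 5 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.399). Cd9, needed for fusion with sperm, rose from 12.9 ± 6.10 to 164 ± 46.1 CPM, and Oosp3, Omt2b and Pla2g4c had log2 fold changes of -2.32, -1.99 and -1.44. Of 9 genes of the 2-cell stage, 1 rose (Tcstv1, 0.64) and 1 fell (Sp110, -1.34), with the same counts adjusted over the list alone (camera adjusted p = 0.905), and Zfp560 and Zscan4d did not pass the test, at -0.50 and 2.76. Zscan4d passed without control replicate 4 (4.85, adjusted p = 0.0164).

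**Figure D2:**
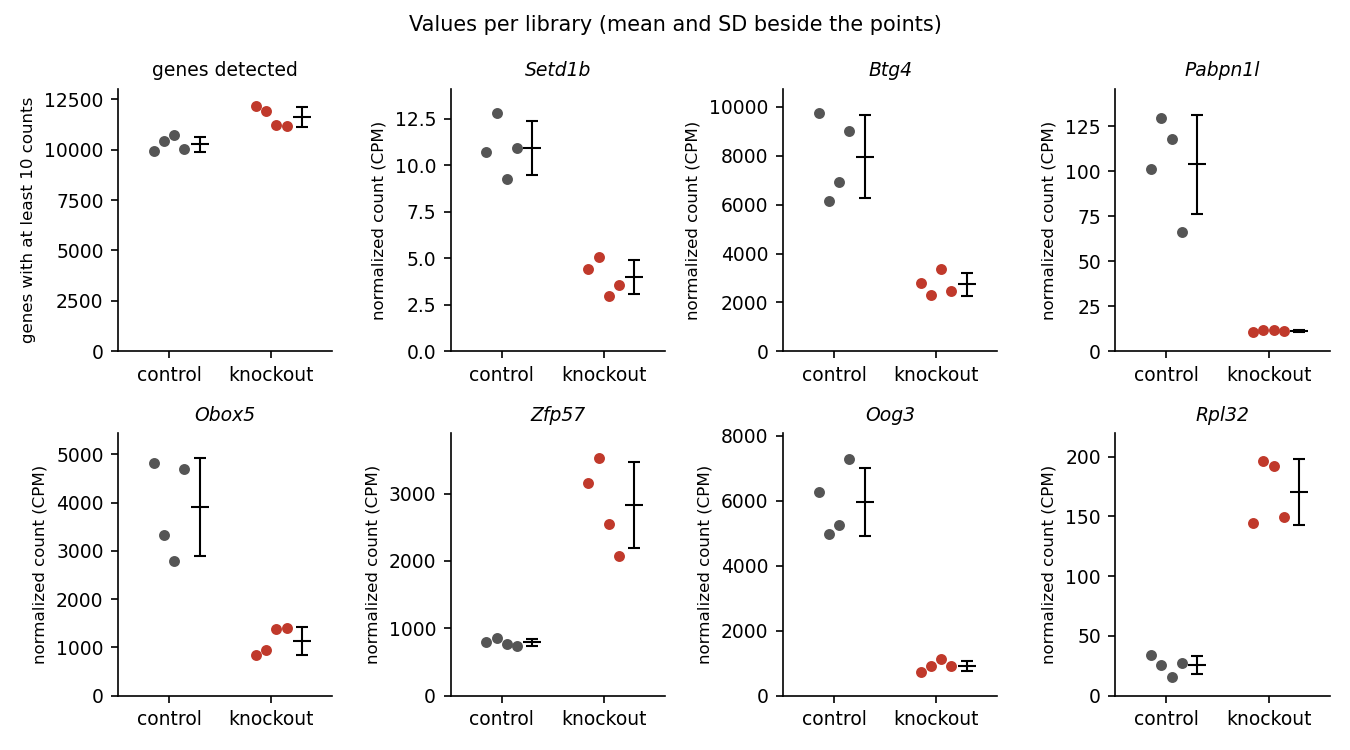
Each point is 1 library, with the group mean and SD (n = 4) drawn beside the points, and every vertical axis starts at 0. The first panel gives genes with at least 10 counts and the others normalized counts in CPM, and in each of the 8 panels the control and knockout libraries do not overlap. The genes shown were picked from those called in these libraries, so their lack of overlap is not a separate result. Among all tested genes, 31.3% had no overlap.

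Genes of the spindle and of meiotic maturation fell more often than they rose. Of 59 tested, 7 rose and 17 fell (8 and 22 adjusted over the list alone; camera adjusted p = 0.00739, and adjusted p = 0.205 with an estimated correlation). Fmn2, an actin nucleator that positions the oocyte spindle, went from 1053 ± 167 to 388 ± 74.1 CPM. Pttg1 (securin) and Cenpa had log2 fold changes of -1.36 and -1.25, and the checkpoint kinase gene Bub1 had one of 2.32. Of 44 genes of DNA methylation and repressive chromatin, 4 rose and 8 fell (4 and 9 adjusted over the list alone; camera adjusted p = 0.0192, and adjusted p = 0.251 with an estimated correlation). The dioxygenase gene Tet3 went from 1768 ± 561 to 750 ± 46.7 CPM. Nsd1 and Rnf2 had log2 fold changes of -0.95 and -0.82, and Setdb1, a histone H3 lysine 9 methyltransferase, rose from 106 ± 36.2 to 307 ± 46.8 CPM. The median log2 fold changes of these 2 lists were -0.32 and -0.34, but 0.067 and 0.065 with library totals as the only scaling, so their sign depended on scaling. Relative to the median of all tested genes, the medians of these 2 lists were -0.43 and -0.44, and -0.43 and -0.43 with library totals as the only scaling. The camera adjusted p-values were 0.0862 and 0.195 there, and 0.0935 and 0.135 among genes with at least 10 CPM in 4 libraries, so neither call held. The medians lay inside the range of random lists matched on length, GC content and abundance, at the 31.0th and 18.8th percentiles of 10000. Of 16 meiotic prophase genes, 0 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.0704), among them Sycp2 (-1.83), Mei4 (-1.28), Sycp3 (-1.22) and Brca2 (-0.88).

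The lists of methyltransferase complexes for histone H3 lysine 4, histone demethylases, zinc finger proteins, the transcription machinery and histones were not called by camera. Of 19 genes of the methyltransferase complexes for histone H3 lysine 4, 3 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.187): Ash2l, a shared core subunit, rose from 24.0 ± 7.47 to 65.2 ± 15.2 CPM, and Psip1, Kdm6a and Bod1l had log2 fold changes of -1.56, -0.95 and -0.94. Of 13 histone demethylase genes, Kdm5c fell (-1.42), also adjusted over the list alone, and 12 did not pass (camera adjusted p = 0.315), including Kdm3a, Kdm6b and Kdm2b at -2.67 (-1.99 without control replicate 4), -0.54 and 0.48. Of 269 zinc finger protein genes of the Krueppel type, 18 rose and 40 fell (17 and 39 adjusted over the list alone; camera adjusted p = 0.315), with Zfp616 at -2.61, Zfp708 at -2.13 and Zfp592 at 1.55. Of 9 Klf genes, Klf7 and Klf17 fell (-1.06 and -1.12), also adjusted over the list alone, and Klf16 and Klf10 did not pass, at 0.62 and -0.48 (camera adjusted p = 0.399). Of 73 genes of RNA polymerase II, Mediator and TFIID, 18 rose and 14 fell (20 and 17 adjusted over the list alone; camera adjusted p = 0.593), with Med26, Polr2d and Gtf2e2 at 3.55, 1.84 and 1.57 and Med27 at -1.33. Of 62 matched replication-dependent histone genes only 8 were tested, of which 3 rose and 1 fell (4 and 1 adjusted over the list alone). The camera adjusted p was 0.187. Hist1h2bc, Hist1h2aa (1.47) and Hist1h1c (4.73, and 5.47 without control replicate 2) rose, and the linker histone gene Hist1h1a fell (-1.72). The kit primes on poly(A) tails, so these values need not reflect the level of histone mRNA as a whole.

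The stress lists were not called by camera. Of 24 heat shock and unfolded protein genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.399), with Hspa8, Pdia4 and Dnaja1 at 1.94, 1.00 and 0.96 and Hspa9 at -0.78. Of 22 genes of the p53 response and apoptosis, 2 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.375), with Chek1, Trp53inp1 and Mdm2 at -1.28, -0.82 and -0.75 and Atr at 0.99. Markers of cumulus and granulosa cells, which surround the oocyte, were scarce: 5 of 30 passed the abundance filter, Esr2 and Cyp19a1 fell (-0.80 and -0.85, both lost with library totals as the only scaling), Kitl and Nts did not pass (-0.40 and -0.89, the latter -1.89 without knockout replicate 2 and 0.029 without control replicate 1), and camera gave an adjusted p of 0.294, with the same counts adjusted over the list alone. Of 26 markers of blood, stroma and oviduct, 3 were tested, too few for camera: Epcam and Pecam1 fell (-3.46 and -0.83), also adjusted over the list alone, and Dcn did not pass (-0.74).

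**Figure D3:**
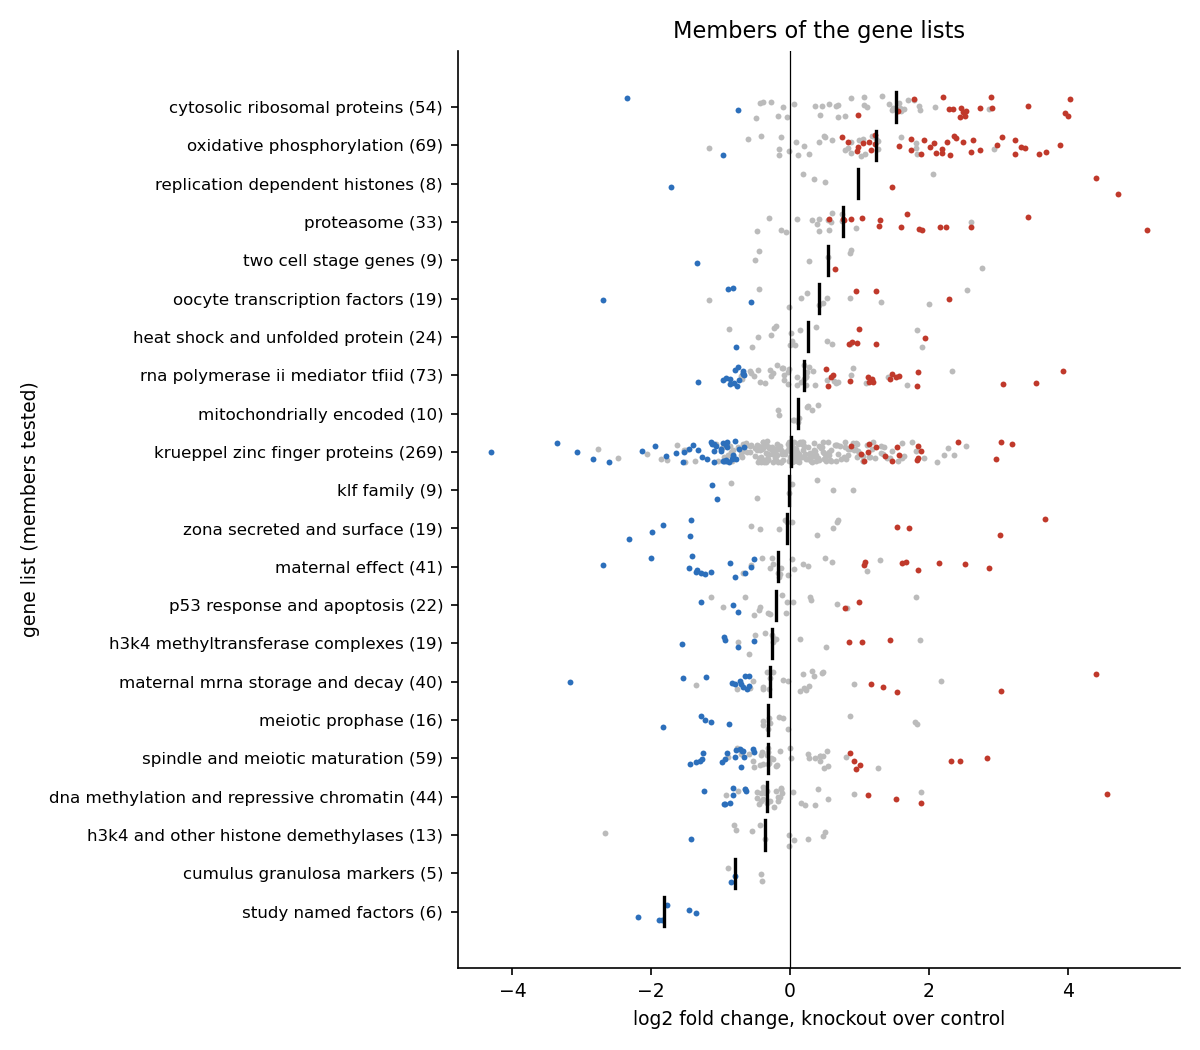
Each point is 1 tested member of a gene list, placed by its log2 fold change of knockout over control, with red for genes that rose, blue for genes that fell and grey for genes that did not pass, and the black bar is the list's median. The medians run from -1.81 for the factors named by the study to 1.52 for cytosolic ribosomal proteins.

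More genes were detected in knockout oocytes. At least 10 counts were found in 11617 ± 490 genes (SD, n = 4) in the knockout and 10269 ± 368 genes in the control libraries, and each knockout library lay above each control library (exact two-sided permutation test, p = 0.0286, the smallest that 4 against 4 allows). The total counts did not favour the knockout, which ran from 9488899 to 11313502 in the knockout and from 11029602 to 13519404 in the control libraries. Mitochondrially encoded transcripts took 6.19% ± 0.739 of the counts in knockout and 4.41% ± 0.970 in control oocytes, a difference that did not reach the threshold (exact permutation p = 0.0571). Ribosomal protein genes took 0.164% ± 0.0171 against 0.0822% ± 0.0102 (exact permutation p = 0.0286).

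The authors' deposited table listed 2709 genes, 1410 with a positive and 1299 with a negative log2 fold change, and 2566 of them (94.7%) were called in the same direction by edgeR here and 0 in the opposite direction. The thresholds differ, since the deposited calls all lie under an adjusted p of 0.01 and the edgeR calls under 0.05. At an adjusted p under 0.01, edgeR called 1391 genes. Of the listed genes, 86 were not tested here. Both sets of calls come from the same 8 libraries, so the overlap is not a replication.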

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

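All tests in this part were chosen after the results were seen, except the rule for outlying libraries. In 9 of 244 groups of 4 libraries, 1 library stood far from the other 3 by Dixon's ratio of its gap to the range, against 12.2 expected by chance. In control oocytes the ratios were 0.954 for Eif4h, where replicate 3 was high, 0.878 for Paip2, 0.843 for Prr32 and 0.837 for Zfp708, where replicate 1 was high, and 0.847 for Kitl, where replicate 4 was low. In knockout oocytes they were 0.846 for Setdb1, where replicate 4 was high, 0.892 for Zfp592, where replicate 1 was high, 0.858 for Bub1, where replicate 2 was high, and 0.903 for Zfp560, where replicate 4 was low. No library measure (detected genes, total counts, mitochondrial, ribosomal protein or top-10 share) had such a library.

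For the counts of genes, the real division of the libraries ranked first. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave 2850 genes, and the highest of the other splits gave 0. The same 1 of 35 held for the 1503 higher and the 1347 lower genes, where the highest other split gave 0 on either side. The other splits mix the genotypes, so the genotype difference widens the spread within their groups. Their 0 is therefore not the number that chance alone would give, and 1 of 35 is the smallest share this test allows. Chance cannot be excluded for the number of gene lists called: 8 of the 35 splits called as many as the real 6, and the highest of the others called 7. The real 6 include the list of factors that the study named on these samples. The 7 other splits that called as many each set 3 libraries of a genotype with 1 of the other, so they keep part of the genotype contrast, and the 18 splits with 2 libraries of each genotype on either side called at most 5.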

How the results depend on the processing

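The length trend and the length and GC trend were chosen after the data were seen. No gene called in both fits had opposite directions. Of the 2850 called genes, called again or not, 7 higher genes turned sign with the length and GC trend removed and 0 in each other fit, where 2338 had a value with at least 10 CPM in 4 libraries, 2836 with thinned libraries and 2849 in DESeq2. Between 1391 and 2848 of the 2850 calls were shared with the same direction. At an adjusted p of 0.01, 1391 genes differed, 747 higher and 644 lower. With library totals only, 2382 were higher and 504 lower, and Setd1b had a log2 fold change of -1.04 (adjusted p = 0.0895, range 0.0002067 to 0.0895 over its alternatives). A 2-fold minimum left 623 lower genes. With each library left out in turn, the count ran from 1849 to 2841 genes, from 1012 to 1597 higher and from 837 to 1244 lower, lowest without knockout replicate 2, and Setd1b ran from -1.57 to -1.33, its call ending without knockout replicate 3 or control replicate 2. Setd1b gave no value with at least 10 CPM in 4 libraries, and camera was not run on DESeq2. The lists called numbered 6, the factors named by the study among them. With an estimated correlation 0 were called, and 14 with fry, which does not compare a list with other genes. The spindle and DNA methylation lists lost the call with library totals only (0.0862 and 0.195) and at 10 CPM (0.0935 and 0.135), where meiotic prophase gained one (0.0475). Maternal effect genes, at 0.0595, passed with no filter (0.00396), with the length trend (0.0147) or both trends removed (0.00992) and with 5 of the 8 libraries left out (0.0239 to 0.0484), and storage and decay genes with no filter (0.00671) and with 4 left out (0.0407 to 0.0498). Meiotic prophase passed without control replicate 2 (0.0386) and histones without control replicate 3 (0.0440). The difference in detected genes ran from 1169.5 to 1496.75 with a library left out, where 3 against 4 cannot reach 0.05 (exact permutation p = 0.0571); it was 1732 at 1 count or more. The deposited calls all lie under 0.01, so a threshold of 0.05 or 0.01 on them gave the same overlap. The threshold of the edgeR calls was left at 0.05 there. Except where named, the cause was not tested.

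The same replicate numbers occur in both groups, but same-numbered libraries did not deviate together (correlations -0.064, -0.0212, -0.117 and -0.0599). The counts thus show no pairing by number, but these correlations cannot exclude a shared collection or preparation. A fit with the replicate block gave 1951 genes, 1090 higher and 861 lower, and 6 lists. Setd1b was at -1.46 and lost its call in that fit (adjusted p = 0.0700).

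Among named genes and in camera's direction for a list, turns were seen only in results that had not passed. Nts was 0.67 with voom quality weights, 0.029 without control replicate 1 and -1.89 without knockout replicate 2, Klf16 was -0.075 with the length and GC trend removed, and mt-Rnr1, mt-Co1, mt-Rnr2 and mt-Nd6 were -0.035, -0.069, -0.14 and -0.16 with the length trend removed. Among lists, camera turned for the mitochondrially encoded genes (adjusted p = 0.953 without control replicate 2, against 0.301 without control replicate 1, 0.163 with the length trend removed), for RNA polymerase II, Mediator and TFIID (0.917 with the length trend and 0.970 with both trends removed) and for 2-cell stage genes (0.985 with library totals only, 0.994 without control replicate 3, against 0.483 without control replicate 4, 0.917 with the length trend removed). Of 102 called named genes besides Setd1b, 11 lost the call with library totals only and 6 with the block. With libraries thinned to the smallest, 2842 genes were called, 2766 of them shared with the 2850, and levels under 3 counts, 0.222 to 0.316 CPM, are not resolved at this depth.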

Other observations

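Of the tests in this part, those of matched random lists, of ribosomal protein pseudogenes, of the 100 most abundant genes and of polyadenylation elements had their predictions written before their results were seen, and the others were chosen after. Among symbol stems, Tcl had the smallest p for an excess of lower genes. All 6 tested Tcl1 genes of a cluster on chromosome 12 fell (Fisher's exact test, adjusted p = 0.00173 over 538 tests of 269 symbol stems), from Tcl1b5 at -1.97 ± 0.20 (SE, n = 4 per group) to Tcl1 at -0.53 ± 0.15 on the log2 scale, where 2.80 are expected among genes of the same abundance decile (permutation p = 0.00889), and Tcl1b1 went from 2160 ± 433 to 630 ± 45.7 CPM (SD). Of 12 Nlrp genes, 8 fell (adjusted p = 0.004), but 5.17 are expected at their abundance and the excess did not pass there (permutation p = 0.0768). Nlrp4f went from 2059 ± 174 to 811 ± 172 CPM, and Nlrp9a (-1.45) and Nlrp4b (-1.35) fell, while Nlrp5 and Nlrp2, both known maternal effect genes, rose by 1.66 and 1.62. The copies in both families are similar, so reads can be split among them, and these genes were picked after their values were seen. Of 14 genes with the stem Ndufa, 8 rose and 1, Ndufa10, fell (-0.97). Fisher's exact test gave an adjusted p of 0.0286 for the rise, and 1.81 rises were expected at the same abundance (permutation p = 9e-05). The permutation p-values were computed only for stems that had passed Fisher's exact test, without adjustment. Both tests count genes as independent, although the Tcl1 genes are similar neighbouring copies. The Rpl stem stood at the threshold of Fisher's exact test and did not pass (adjusted p = 0.05001). A second way to cut symbols into stems, run in between, put it just under the threshold, and it is not counted here for that reason.

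The rise of oxidative phosphorylation, ribosomal protein and proteasome transcripts was set against length, GC content, abundance and pseudogenes. With a length and GC trend removed from each library, the medians of the lists stayed 0.91 ± 0.20, 1.10 ± 0.25 and 0.69 ± 0.19 (bootstrap SE) above the median of all tested genes, which argues against such a trend as the whole cause. Against 10000 random lists matched on length, GC content and abundance the first 2 medians lay above every list and the third at the 99.9th percentile. The bootstrap SE and the random lists treat genes as independent and leave out the spread between oocytes. Genes of a list can move together, and the camera calls of these lists did not hold with an estimated correlation. The 225 named ribosomal protein pseudogenes did not lose reads: their summed CPM was higher by 41.0 in the knockout (129 ± 14.1 against 88.5 ± 23.9, exact permutation p = 0.0286). An effect of the knockout, for example on clearance of maternal mRNA, may account for the rise and stays open as an untested hypothesis, as does a difference in collection or amplification between the genotypes, for which the labels give no batch.

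More genes were detected in knockout libraries, and direction followed abundance: in the most abundant decile of tested genes 74 rose and 559 fell, and in the fifth decile 222 rose and 47 fell. Depth was not the source, since the difference was 1562 genes with all libraries thinned to 1 total. Nor was it a few genes taking the counts, since it was 1459 genes with the 100 most abundant genes left out. The markers argue against cumulus and granulosa RNA as the whole source: of the 5 tested, 0 were higher in the knockout, and of the 25 below the filter 13 had 0 counts in all libraries, among them Inha, Fst, Tnfaip6 and Ptx3. A trace stays open. Esr2 and Cyp19a1 are so high in control oocytes that they would hide a small share. The markers below the filter summed to 140 counts in knockout and 67 in control libraries. More counts fell in the knockout for 9 of them and in the control for 3. Among the 9 were Has2 at 29 against 4, Btc at 27 against 0 and Nr5a1 at 10 against 0. Fshr at 8 against 2 and Cyp11a1 at 33 against 19 were also among them. The 3 were Ptgs2 at 12 against 28, Grem1 at 0 against 5 and Npr2 at 0 against 2. The counts of Btc and Nr5a1 came from 1 knockout library each, as did those of Fshr in the knockout, and the number of these markers with at least 10 counts per library, 1.75 against 0.5 on average, did not pass (exact permutation p = 0.143). Scarce genes in general tended to be higher in the knockout, with a median log2 fold change of 0.747 in the least abundant decile of tested genes. With no filter, the median of the whole cumulus and granulosa list was 0.347, against 0.347 for all genes, and in DESeq2 0.806 against 0.321. An excess particular to these markers is therefore not shown. In knockout replicate 1 the immune cell markers Tyrobp, Cd52 and Fcer1g had 15, 14 and 11 counts, against 0 in the control libraries. Uneven amplification of the 2 groups, or a genotype effect, could each give this pattern, and no value here separates them.

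A candidate explanation for the lower genes is altered cytoplasmic polyadenylation, since the kit primes on poly(A) tails. An element of that kind (the motifs UUUUAU or UUUUAAU in the last 150 nucleotides) occurred in 38.2% of 1254 lower, 26.6% of 6839 uncalled and 19.8% of 1259 higher genes with a searchable 3' untranslated region. Within strata of abundance, length and AU content the excess of the lower genes was 2.84 percentage points, which did not pass (permutation p = 0.0766), so it cannot be told apart from no effect. The deficit among higher genes was -5.32 percentage points (permutation p = 8e-05), a result for which no prediction was written. Genes are not independent replicates in either test.

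Of 35 tested genes within 1 Mb of Setd1b, 6 rose and 2 fell, 22.9% against 25.8% of all tested genes.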
